A study of Arabidopsis thaliana with 209 samples.

How the data were processed

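The data were RNA-seq libraries from 209 Arabidopsis MAGIC lines, 1 library per line, made from polyadenylated RNA of pooled aerial seedlings grown at 20 °C, without strand information, per the labels. Reads were processed by the authors against TAIR10, per the submitters' processing notes. Whether fragments of alleles that differ from that build were lost was not tested, so a low value means few counted fragments. The aligner and the counting program are not given in the sources used here. Both deposited tables have lines as rows and 65238 features as columns: 33323 nuclear genes, 31189 transposable elements, 447 further genes and 279 organelle genes. Organelle genes were at 0 in every line, so the planned relation with their share of FPKM is void. A total of 355 columns had no value.

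The first deposited table holds FPKM, per its name, at 1/1000 of the usual scale, and values were multiplied by 1000. Values of each gene were whole multiples of what 1 fragment is worth, which gave library totals and counts: 100% of the values above 0 of nuclear genes with a recovered length were whole within 0.02. Recovered lengths of expressed genes were a median of 0.939 times the annotated gene span, so they may include introns. No count model was fitted. The second deposited table holds a score: for each feature, the values fitted a normal quantile over libraries of the feature's rank within its line, on a grid of 312 libraries, of which 209 were given. The median rho between this score and the within-line rank of recovered counts was 0.99987.

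Expression was analysed as log2(FPKM + 1) for genes with a median of at least 1 FPKM. The fixed gene pairs and the on/off genes were not held to this minimum. Spread is the SD over lines with a 95% interval from 1000 bootstrap samples of lines. Excess SD is the SD divided by a running median over 501 genes of like mean. The 25 gene lists, the 47 gene pairs, and the planned tests and alternatives were fixed before the data were examined, and changes and additions made later are named as such. Lists with at least 5 expressed members were compared with 10000 random lists matched on mean expression in 20 bins, two-sided for spread and one-sided for mean pairwise r. Relations between list scores (the mean z of expressed members) and between genes used Pearson's r and Spearman's rho with two-sided permutation tests (100000 permutations), and r without the 2 lines farthest from the median. Adjusted p values are Benjamini-Hochberg within each family. The plan gave no pooled r where a gene of the pair was an on/off gene. Later this was extended to genes with a gap of at least 0.5 in log2 values, with at least 6 lines on each side. Tests within the clusters parted by such gaps were also added later. On/off genes were below 0.1 FPKM in at least 10 lines, at or above 2 FPKM in at least 10, and in between in at most 10% of lines. P values from permutations and from shuffles of line number describe the spread over these libraries only. Those from random lists and shuffled gene order hold the lines fixed and describe the spread over genes in these libraries. Genes of most lists varied together more than those of random lists, so p values for list spread may be too small.

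The named genes were the 10 with the largest and the 10 with the smallest SD (the latter at a median of at least 10 FPKM), the 10 with the largest excess SD at that median, the 10 on/off genes with the highest level in expressing lines, in each list the 2 most and the 1 least variable by excess SD, on/off genes in a list, genes of the fixed pairs, and the 10 adjacent pairs with the highest r. A few genes that led a component were chosen after their values were seen. Adjacency was planned to be tested by circular shifts, which leave neighbours in place, so gene order was shuffled within chromosomes 1000 times instead. Gene names, order, overlap and strand came from the TAIR10.1 annotation, which may differ from the authors' build, and no coordinates are given. Similar genes were found with BLAST+ 2.17.0 (hits of at least 100 bases; near-identical at 95% identity, similar at 80%). Hits on either strand counted, so where a gene below has a near-identical gene and overlaps another, these may be the same gene.

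Library sets were found after the data were seen, by parting the first component at its 2 widest gaps that left at least 6 lines in each set. Alternatives were a pseudocount of 0.1, no expression filter beyond a value above 0 in 50% of lines, upper quartile scaling, leaving out the 10 lines farthest from the median profile, the median absolute deviation, Spearman correlation, removal of 10 components, the rank-based table, matching on length, other thresholds and other sets of neighbours. Removal of set means, the fragment minimum for on/off genes, and leaving out overlapping and similar neighbours together were added later.

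No 2 libraries were the same: the most alike pair had a chi-square per gene of 4.88, where 1 is sampling noise. Depth gave a median of 170 fragments per expressed gene, and counting made up a median of 13.9% of variance and 42.0% at the 95th percentile of genes. The steps were tested on simulated data. With 16964 genes, lists given an extra SD of 0.5 in log2 were found in 100% of cases and unchanged lists in 6.5%. Lists given a shared factor of SD 0.2 were found in 100% and unchanged lists in 4%. Of 200 pairs of normal values simulated with a correlation of 0.3, 99% were found, and of 200 unrelated pairs 2%. With 16964 genes, all 200 genes of at least 5 FPKM silenced in 20 lines were called on/off. Another 5 were called, none of them with at least 10 fragments. Simulated genes varied independently apart from the seeded changes, without library sets, so these rates may not hold for the real data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.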

Results

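RNA from aerial parts of Arabidopsis thaliana seedlings was measured in 209 inbred MAGIC lines, which descend from intercrosses of 19 founder accessions. Each line had 1 library, made from a pool of seedlings at the fourth true leaf stage. The labels gave 1 kind of sample and no contrast, so the values below describe how genes differed among lines. No line had a second library, and the spread among lines therefore holds inherited, environmental and technical parts that could not be separated. Libraries held between 4145686 and 30201761 fragments (median 10963247). Among 33130 nuclear genes with values, 16964 had a median of at least 1 FPKM (fragments per kilobase of the gene length used in the deposited values, scaled to library size), and 13225 reached 1 FPKM in every line. A line had 17036 ± 212 genes (SD, n = 209) at or above 1 FPKM.

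The libraries fell into 3 sets along the first principal component of expression, which held 9.99% of the variance (95% bootstrap interval 9.24 to 12.1). Set A had 104 lines, set B 96 and set C 9. Among the 15 genes with the highest correlation to this component was the histone gene HTB9 (AT3G45980), and among the 15 with the lowest were FBA2 (AT4G38970), a chloroplast aldolase, and the ribosomal protein gene RPS5A (AT3G11940). Sets A and B followed line number: 194 of the 200 lines of sets A and B lay on their set's side of line number 191, more than in any of 1000 shuffles of line number (p = 0.000999, the smallest the shuffles can give). All 9 lines of set C had numbers above 191, like most of set A (median line numbers 295 and 303.5), so line number did not part C from A, although these sets lay at opposite ends of the component. Differences between sets made up 10.7% of all variance, a median of 8.54% per gene, and over 50% in 651 genes. The labels named no batch, and values within sets A and B therefore stand beside the relations below. Set C, with 9 lines, was not given values of its own.

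**Figure D1:**
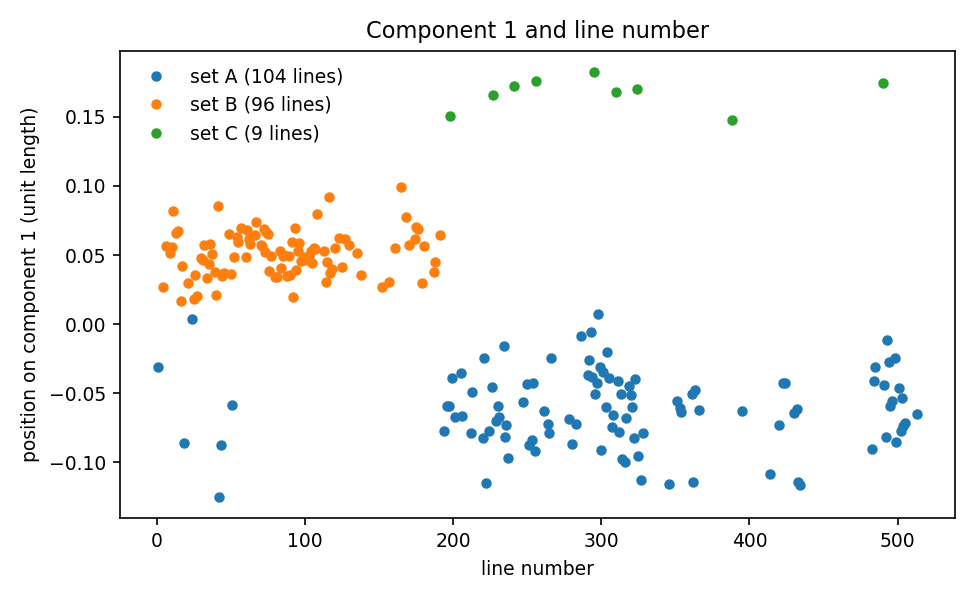
Position of each of the 209 lines on the first component of log2(FPKM + 1) (vertical axis, unit length) against line number (horizontal axis), with colours for the 3 library sets. Set B lies at line numbers up to 191, and 98 of the 104 lines of set A and all 9 of set C lie above it.

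Glucosinolate and defence genes were among those that differed most among lines. The largest SDs of log2(FPKM + 1) belonged to AOP2 (AT4G03060, 3.46, 95% bootstrap interval 3.32 to 3.56) and AOP3 (AT4G03050, 3.44, 3.34 to 3.51), neighbouring genes that modify the side chain of aliphatic glucosinolates. GSL-OH (AT2G25450), which hydroxylates these side chains, followed with an SD of 3.24. Next came the myrosinase gene TGG2 (AT5G25980, 2.86), AT3G62460 (2.79), the epithiospecifier gene ESP (AT1G54040, 2.76) and the pathogenesis-related gene PR1 (AT2G14610, 2.75). AT2G25510 (2.67), ECS1 (AT1G31580, 2.28) and AT5G42530 (2.21) completed the 10 largest. PR1 ranged from 0 to 6323 FPKM with a median of 6.11, and ESP from 6.94 to 2665 FPKM with a median of 909. Relative to genes of like level, AT4G05049 (SD 2.21), AT3G62530 (2.18) and the thionin gene THI2.2 (AT5G36910, 2.11) were also among the 10 most variable genes with a median of at least 10 FPKM. ESP, AT3G62460 and AT3G62530 each have 1 near-identical gene, so fragments may have been shared and their values are uncertain. The order depended on the measure of spread: by the median absolute deviation AOP2 stood at 1.26, ESP at 1.07, AT3G62460 at 1.03 and AT3G62530 at 0.41, below TGG2 (3.49), AT4G05049 (3.16), AOP3 (2.72) and ECS1 (2.61).

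Most genes varied little. The median SD was 0.25, 170 genes had an SD above 1 and 14 an SD above 2. The smallest SD at a median of at least 10 FPKM was that of AT1G09130 (0.10), with 76.6 ± 5.50 FPKM (SD, n = 209). AT2G37660, TIM (AT2G21170), AT5G23040, AT3G42050, AT2G17190 and AT5G58330 each had an SD of 0.11, as did APG1 (AT3G63410), and SEU (AT1G43850) and LTO1 (AT4G35760) had 0.12. Of these 10, 2 stayed among the 10 smallest after upper quartile scaling. AT3G42050 and SEU each have 1 near-identical gene, and AT2G37660, TIM, AT5G58330, APG1, SEU and LTO1 overlap another annotated gene, so their values are uncertain. Fragment counting alone accounted for a median of 13.9% of a gene's variance. With a pseudocount of 0.1, which gives low values more weight, 589 genes had an SD above 1.

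**Figure D2:**
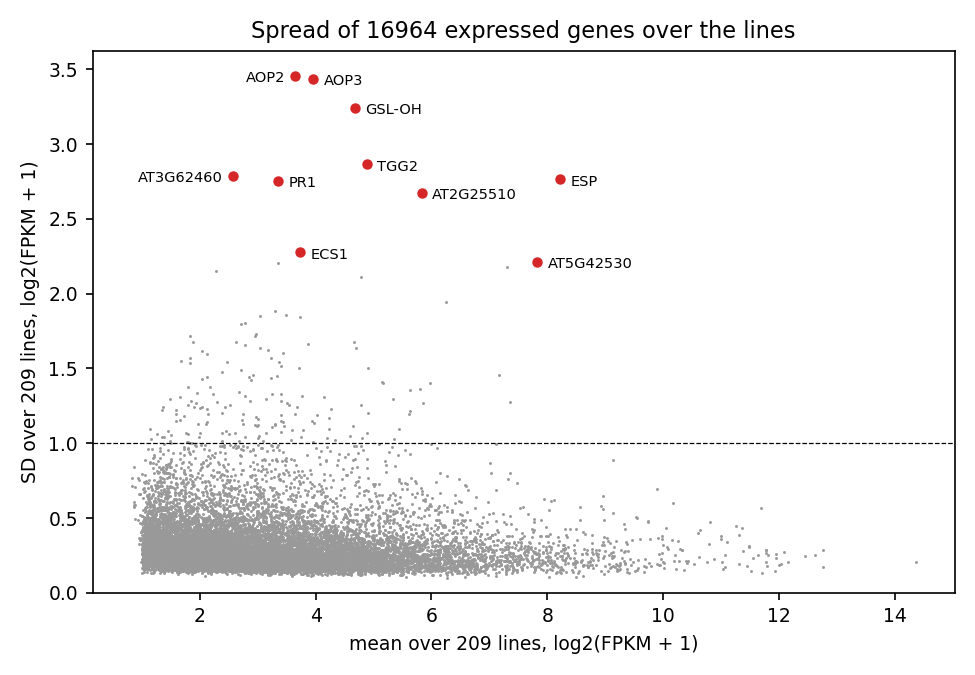
SD against mean of log2(FPKM + 1) over 209 lines for each of 16964 expressed genes (points); the 10 genes with the largest SD are named and the dashed line marks an SD of 1. AOP2 and AOP3 stand highest, at 3.46 and 3.44.

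In all, 13 groups were more variable than genes of like level, among 20 fixed gene lists with at least 5 expressed members. Glucosinolate hydrolysis genes had a median SD 5.87 times that of genes of like level, with 4 of only 5 expressed members above 1. Salicylic acid defence genes had 3.33 times, with 13 of 14 expressed members above 1. Rapid wound and touch response genes (2.97, 15 of 15), cold and dehydration genes (2.91, 12 of 12), flavonoid and anthocyanin genes (2.40, 15 of 15), aliphatic glucosinolate genes (2.30, 23 of 24) and jasmonate and ethylene defence genes (2.14, 13 of 14) followed. These 7 groups had p = 0.0002 against 10000 random lists matched on expression, the smallest this two-sided test can give, and an adjusted p of 0.0005 over 20 lists. Loci with known natural variants had the same adjusted p (2.59, 15 of 17), and this list shares AOP2, AOP3, ESP and GSL-OH with the glucosinolate lists. Dark and sugar starvation genes (2.44, adjusted p = 0.00178), clock genes (1.70, adjusted p = 0.0024), iron homeostasis genes (1.51, adjusted p = 0.0153), NLR immune receptors (1.33, adjusted p = 0.0387) and phosphate starvation genes (1.84, adjusted p = 0.0403) completed the 13.

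Within these groups the named members spread unequally, and the least variable members below are those with the smallest SD for their level. In salicylic acid defence, PR1 (SD 2.75) and PR2 (AT3G57260, 1.55) varied most and the receptor gene NPR1 (AT1G64280, 0.24) least. The vegetative storage genes VSP2 (AT5G24770, 1.41) and VSP1 (AT5G24780, 1.28) led the jasmonate list, whose least variable member was JAZ10 (AT5G13220, 0.28, and 0.49 with a pseudocount of 0.1). In the cold list RD29A (AT5G52310, 0.93) and COR15B (AT2G42530, 0.87) stood above COR413-PM1 (AT2G15970, 0.32). ERF104 (AT5G61600, 1.02) and TCH3 (AT2G41100, 0.97) led the wound and touch list, with WRKY53 (AT4G23810, 0.41) lowest. DFR (AT5G42800, 0.77) and UF3GT (AT5G54060, 0.69) led the flavonoid list, and F3PRIMEH (AT5G07990, 0.37, and 0.63 with that pseudocount) was lowest. Among clock genes ELF4 (AT2G40080, 0.97) and FKF1 (AT1G68050, 0.70) varied more than PRR7 (AT5G02810, 0.19). The iron regulators IMA1 (AT1G47400, 0.86) and IMA2 (AT1G47395, 0.75) exceeded PYE (AT3G47640, 0.22), and AT4 (AT5G03545, 0.92) and SPX1 (AT5G20150, 0.51) exceeded SQD1 (AT4G33030, 0.23) in the phosphate list. DRM1 (AT1G28330, 0.78) and DIN10 (AT5G20250, 0.70) stood above NYE1 (AT4G22920, 0.25), and the receptors RPP5 (AT4G16950, 1.07) and DSC1 (AT4G12010, 0.62) above RRS1 (AT5G45260, 0.26). With that pseudocount these receptors had SDs of 1.94, 0.94 and 0.40. RPP5 has 3 near-identical genes, and COR15B, WRKY53, DSC1 and FMOGS-OX5 have 1 each. These 4 and NPR1, FKF1 and DIN10 also overlap another annotated gene, and the values of all 8 are uncertain. PEN2 (AT2G44490, 0.24), FMOGS-OX5 (AT1G12140, 0.15) and CRY2 (AT1G04400, 0.19) were the least variable members of glucosinolate hydrolysis, aliphatic glucosinolates and known natural variants.

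The other 7 lists did not pass. These were light harvesting and carbon fixation (1.06, adjusted p = 0.561), cytosolic ribosome (1.08, 0.458), cell division (0.972, 0.803), indolic glucosinolates (1.56, 0.0617), flowering time (1.19, 0.305), reference genes (0.849, 0.191) and stomatal lineage and trichome markers (1.15, 0.458). Their extremes included LHCB1.2 (AT1G29910, SD 0.47), RBCS2B (AT5G38420, 0.46) and PSBO1 (AT5G66570, 0.13), and SOC1 (AT2G45660, 0.63), MAF3 (AT5G65060, 0.55) and FCA (AT4G16280, 0.14). With set means removed LHCB1.2 had an SD of 0.27, and with a pseudocount of 0.1 MAF3 had 1.098. The indolic enzymes CYP79B2 (AT4G39950, 0.61) and CYP79B3 (AT2G22330, 0.48) exceeded SOT16 (AT1G74100, 0.27). Among reference genes UBQ10 (AT4G05320, 0.34) and UBC21 (AT5G25760, 0.29) varied more than UPL7 (AT3G53090, 0.16). In the ribosome list RPL27AC (AT1G70600, 0.35) and RPS13A (AT4G00100, 0.17) marked the ends, in the cell division list CDC20.1 (AT4G33270, 0.37) and PCNA1 (AT1G07370, 0.19), and among stomatal and trichome markers EPF2 (AT1G34245, 0.43) and GL2 (AT1G79840, 0.22). LHCB1.2, CDC20.1, UBC21 and GL2 have a near-identical gene, and UBC21, UPL7, RPS13A and GL2 overlap another gene, so these values are uncertain. Heat shock, shoot meristem, root, floral organ and seed storage lists had 4, 2, 1, 1 and 0 expressed members and were not tested. The call for phosphate starvation was lost when random lists also matched gene length (adjusted p = 0.172) or without the expression filter (0.446), and that for NLR receptors was lost without the 10 lines farthest from the median profile (0.0709) or with the median absolute deviation (0.0983). Indolic glucosinolates passed without the expression filter (adjusted p = 0.0380).

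**Figure D3:**
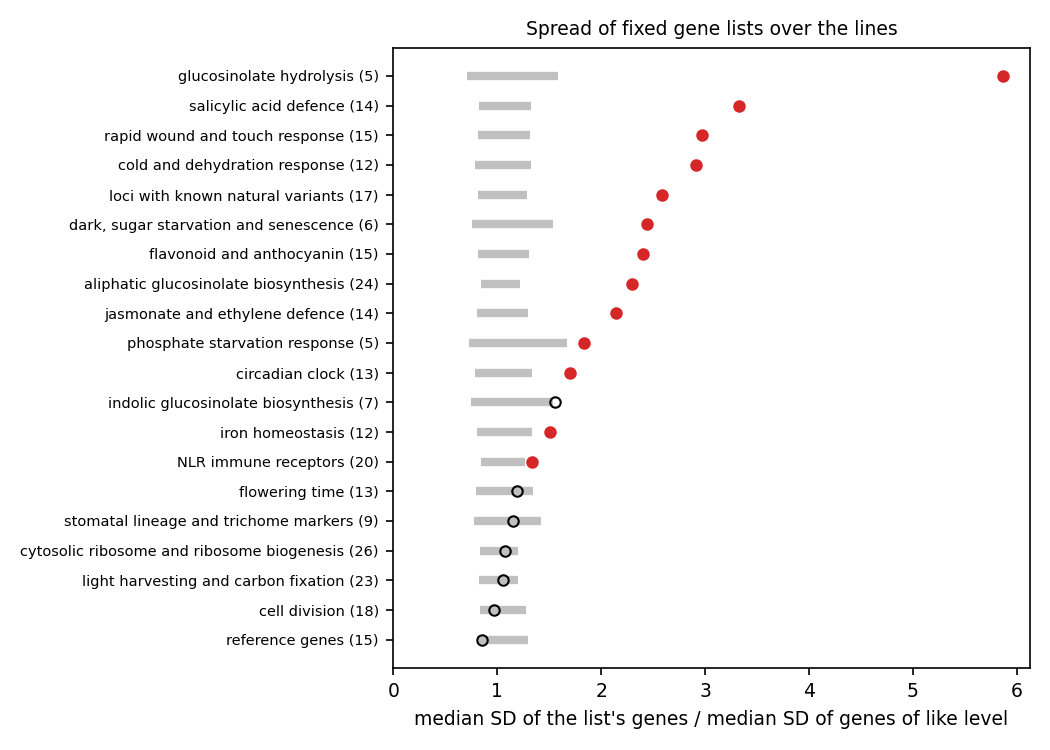
Median over each list's expressed genes (number in brackets) of the SD relative to genes of like level (points) and the range holding 95% of 10000 matched random lists (grey bars). Filled red points mark the 13 lists past an adjusted p of 0.05, and glucosinolate hydrolysis stands highest at 5.87.

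In most lists the mean pairwise r of members over the lines was higher than in random lists. Salicylic acid defence genes had a mean pairwise r of 0.515, and all 91 pairs were above 0. Wound and touch genes (0.481), flavonoid genes (0.450), cold genes (0.428), aliphatic glucosinolate genes (0.377), ribosome genes (0.371), cell division genes (0.257) and jasmonate genes (0.251) also exceeded random lists, which had medians from 0.00453 to 0.0661 for these 8 lists. All 8 had p = 0.0001, the smallest this one-sided test can give, and an adjusted p of 0.00025. Another 9 lists passed: indolic glucosinolates (0.356), dark and sugar starvation (0.269), stomatal and trichome markers (0.259), phosphate starvation (0.245), NLR receptors (0.201), light harvesting (0.178), flowering time (0.154), reference genes (0.112) and the clock (0.106). Glucosinolate hydrolysis (0.0646, adjusted p = 0.217), iron homeostasis (0.0568, 0.270) and known natural variants (-0.00515, 0.975) did not pass. In the clock list, which passed, 55.1% of 78 pairs were above 0, and r ranged from -0.826 to 0.856. Light harvesting had 68.8% of pairs above 0 and reference genes 67.6%. The scores of these lists therefore average some genes that moved in opposite directions. The flowering time call was lost with the mean of each library set removed (adjusted p = 0.116), the clock call without the expression filter (0.437) and the light harvesting call in the rank-based table (0.112). Iron homeostasis passed with upper quartile scaling (adjusted p = 0.0464), with 10 components removed (0.00929) and in the rank-based table (0.0409).

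Defence scores moved together, and ribosome and starvation scores moved apart. Over 209 lines the mean score of salicylic acid defence genes rose with that of NLR receptors (r = 0.722, rho = 0.682; 0.699 without the 2 farthest lines; 0.719 in set A and 0.772 in set B). Clock and cold scores were also related (r = 0.513, rho = 0.516; 0.515 without the 2 lines; 0.551 and 0.450 in sets A and B), as were jasmonate and flavonoid scores (r = 0.461, rho = 0.404; 0.441; 0.555 and 0.407). The dark and sugar starvation score fell as the flavonoid score rose (r = -0.549, rho = -0.510; -0.521 without the 2 lines; -0.603 in set A and -0.462 in set B). It also fell as the ribosome score rose (r = -0.542, rho = -0.526; -0.537; -0.422 and -0.637). Each of these relations had a permutation p of 1e-05 for r and for rho, the smallest that 100000 permutations can give, and adjusted p of 4.86e-05 and 5.23e-05 over all pairs of 17 lists. With 10 components removed the calls were lost for salicylic acid defence with NLR receptors (r = 0.0903, adjusted p = 0.412), clock with cold (0.0147, 0.913), jasmonate with flavonoids (0.0159, 0.907) and ribosome with dark starvation (-0.0341, 0.818). In all, 74 pairs passed, 41 of them positive and 33 negative, and 72 passed by rho.

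With the mean of each set removed, 64 pairs passed, 61 of them in common. Flowering time with reference genes then changed sign, from -0.264 to 0.180 (adjusted p = 0.0199; 0.201 in set A and 0.199 in set B). The pooled relation of ribosome and flowering time scores (r and rho = -0.246, adjusted p = 0.000874 and 0.00108) ended when set means were removed (adjusted p = 0.99981), with -0.173 in set A and 0.155 in set B. With upper quartile scaling 73 pairs passed, of which 31 (42.5%) were positive, against 55.4% without it and 41.8% (28 of 67 pairs) with the rank-based values. Light harvesting fell with the ribosome score (r = -0.469, rho = -0.412; -0.442 without the 2 farthest lines; -0.367 in set A and -0.601 in set B) and with reference genes (r = -0.516, rho = -0.525; -0.508; -0.526 and -0.629), at the same p values. Neither light harvesting relation passed after that scaling (r = -0.106 and -0.0502) or with 10 components removed (0.0796 and -0.140).

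Several fixed pairs of genes with known links were related over the lines. The flowering repressor FLC (AT5G10140) and its target SOC1 moved in opposite directions (r = -0.652, rho = -0.563; -0.627 without the 2 farthest lines; -0.737 in set A and -0.786 in set B). The clock genes CCA1 (AT2G46830) and TOC1 (AT5G61380) were also opposed (r = -0.476, rho = -0.452; -0.460; -0.498 and -0.511), while GI and FKF1 rose together (r = 0.663, rho = 0.688; 0.660; 0.706 and 0.673). DFR rose with LDOX (r = 0.837, rho = 0.786; 0.814; 0.882 and 0.858) and with its regulator PAP1 (r = 0.685, rho = 0.612; 0.655; 0.760 and 0.599). CBF1 rose with CBF2 (r = 0.744, rho = 0.674; 0.711; 0.770 and 0.742), and MAM1 fell as its neighbour MAM3 rose (r = -0.344, rho = -0.359; -0.338; -0.424 and -0.267). These relations had a permutation p of 1e-05 for r and for rho, with adjusted p of 1.65e-05 and 1.58e-05 over 38 pairs. The call for CCA1 with TOC1 was lost with 10 components removed (r = -0.117, adjusted p = 0.111). FLC and CBF1 had medians of 0.666 and 0.487 FPKM, below the minimum of 1 FPKM, which was not applied to fixed pairs.

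Of 47 fixed pairs, 38 had a pooled r, and 35 of these passed, 29 positive and 6 negative. The pairs that did not pass were VSP2 with PDF1.2A (r = 0.0525, rho = 0.00992, adjusted p = 0.450 and 0.909, 0.0335 without the 2 farthest lines, 0.0580 in set A and -0.00275 in set B), MYB28 with CYP79F1 (r = 0.134, rho = 0.106, adjusted p = 0.0551 and 0.142, 0.120 without the 2 lines, -0.0228 and 0.267 in sets A and B) and FER1 with BHLH39 (r = -0.0769, rho = 0.00565, adjusted p = 0.277 and 0.935, 0.0258 without the 2 lines, 0.0221 and 0.0129 in sets A and B). FRI with FLC (r = 0.163, rho = 0.0698, adjusted p = 0.0199 and 0.344, 0.155 without the 2 lines, 0.120 and 0.0887 in sets A and B) and IMA1 with BHLH100 (r = 0.145, rho = 0.0926, adjusted p = 0.0381 and 0.204, 0.155 without the 2 lines, -0.0736 and 0.0808 in sets A and B) passed by r and not by rho. The call for FRI with FLC was also lost with a pseudocount of 0.1 (adjusted p = 0.211), without the 10 farthest lines (0.107), with set means removed (0.0866), with 10 components removed (0.472) and in the rank-based table (0.145). That for IMA1 with BHLH100 was lost with the pseudocount (0.0799), with upper quartile scaling (0.0673) and without the 10 lines (r = 0.0196, adjusted p = 0.783). With 10 components removed MYB28 with CYP79F1 passed in the negative direction (r = -0.189, adjusted p = 0.00977). With set means removed 32 pairs passed. MAF2 and MAF3 had r = 0.187 pooled (rho = 0.263, adjusted p = 0.00753 and 0.000152; 0.182 without the 2 farthest lines) but -0.195 in set A and -0.251 in set B. Its call was lost with the pseudocount (adjusted p = 0.0510), with upper quartile scaling (0.0535), without the 10 lines (0.132) and in the rank-based table (0.156), and was negative with set means removed (r = -0.243, adjusted p = 0.000479) or 10 components removed (-0.282, 8e-05). RBCS1A and LHCB1.1 had r = -0.300 pooled (rho = -0.361, adjusted p = 4.56e-05 and 1.58e-05; -0.337 without the 2 lines), and no relation held within sets (-0.108 and 0.111). The relation of BHLH38 with BHLH39 (r = 0.287, rho = 0.0514, adjusted p = 0.00213 and 0.485) rested on the 2 farthest lines, without which r was 0.0583, and r was 0.111 in set A and -0.0736 in set B. LDOX and LHCB1.1 each have 1 near-identical gene, and FKF1, FRI, FER1 and BHLH38 overlap another gene, so their values are uncertain. Several of these genes were near the floor, with medians of 0.895 FPKM for FRI, 0.365 for PDF1.2A and 0.0762 for BHLH39. BHLH38 and BHLH100 had medians of 0.

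Most lines had high values of either AOP2 or AOP3. In 53.6% of lines AOP3 stood at 143.7 ± 68.2 FPKM (SD) and AOP2 at 0.558 ± 0.498, and in 43.5% (91 lines) AOP2 stood at 215 ± 127 and AOP3 at 0.154 ± 0.261. In 4 lines both were in the upper cluster and in 2 both in the lower, at 5.66 FPKM for AOP2. ESP was also split, with 63 lines at 17.3 ± 4.88 FPKM and the other 69.9% of lines at 1119 ± 454. The glucosinolate regulator MYB29 (AT5G07690) was below 0.1 FPKM in 11 lines and had a median of 14.3 FPKM in the lines at or above 2 FPKM. PR1 was at 2671 ± 1892 FPKM in 7 lines and 36.6 ± 81.5 in the others.

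Because of these clusters the 9 pairs that include PR1, MYB29, AOP2 or ESP were tested only within clusters, in 17 relations. The plan set aside only pairs with an on/off gene, here those with MYB29. The other exclusions and the tests within clusters were added later. In the 199 lines with lower PR1 and PR2 both rose together (r = 0.684, rho = 0.658, permutation p = 1e-05, adjusted p = 4.25e-05 for each; 0.675 without the 2 farthest lines, 0.616 in set A and 0.718 in set B). MYB29 and its target BCAT4 were related in the 194 lines of the upper MYB29 cluster (r = 0.323, rho = 0.404, permutation p = 2e-05 and 1e-05, adjusted p = 6.8e-05 and 4.25e-05; 0.296 without the 2 farthest lines, 0.309 in set A and 0.342 in set B). In the 15 lines of the lower cluster they did not pass (r = 0.381, rho = 0.00638, adjusted p = 0.229 and 0.984; -0.167 without the 2 lines, 0.555 in set A). ESP and ESM1 did not pass in the lower ESP cluster (r = 0.0752, rho = 0.120, adjusted p = 0.590 and 0.452, 0.0422 without the 2 farthest lines, 0.0202 in set A and 0.217 in set B) or the upper (r = 0.0671, rho = 0.117, adjusted p = 0.474 and 0.225, 0.0543, -0.0154 and 0.127). BCAT4 and ESP have a near-identical gene, and BCAT4 overlaps another gene, so their values are uncertain.

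**Figure D4:**
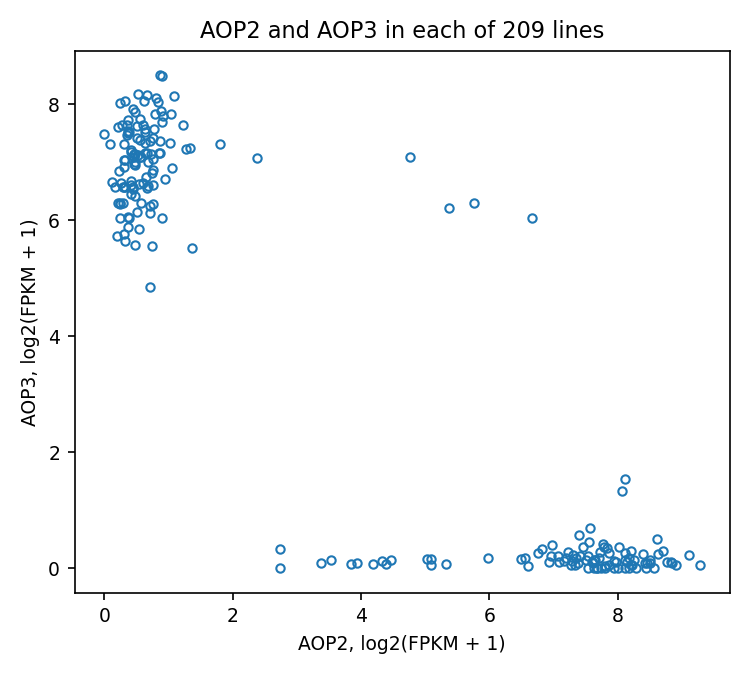
AOP3 against AOP2, each as log2(FPKM + 1), with 1 point per line (209 lines). In 53.6% of lines AOP3 is high and AOP2 low, in 43.5% the reverse.

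Besides MYB29, 71 genes were below 0.1 FPKM in at least 10 lines, at or above 2 FPKM in at least 10, and in between in at most 10% of lines. Without the limit on lines in between, 638 genes met both minimums. The highest levels in the lines with expression were those of AT4G25690 (73.3 FPKM, 10 lines), the Sadhu element SADHU1-1 (AT2G10410, 56.1 FPKM, 18 lines) and AT2G37435 (41.6 FPKM, 12 lines). AT5G39640 (21.8 FPKM, 46 lines), AT4G12100 (21.4, 12), AT5G28919 (20.6, 30), AT5G24735 (18.3, 187), AT4G20210 (16.5, 34) and AT1G14250 (16.4, 188) followed, with MYB29 at 14.3 FPKM. AT4G25690 ranked first, but its 73.3 FPKM rested on under 1 fragment at the median depth (0.804), so neither its level nor its off lines are informative. Of the 72 genes, 53 had at least 10 fragments at their level in expressing lines, and 35 of these were protein coding and 13 pseudogenes. SADHU1-1 and AT5G28919 each have 1 near-identical gene and overlap another gene, which may be the same gene, so their values are uncertain. The count moved with the definition, from 35 to 168 over the alternatives.

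Neighbouring genes varied together. Over 11216 pairs of adjacent expressed genes the mean r was 0.144, against 0.0499 for pairs on different chromosomes and at most 0.0550 in 1000 shuffles of gene order (one-sided p = 0.000999, the smallest the shuffles can give). With set means removed the mean was 0.127 (p = 0.000999). The 8728 pairs that neither overlapped nor had similar sequence had a mean of 0.124, which fell to 0.0871 at 2 gene steps and 0.0532 at 11 to 20 steps. The 10 pairs with the highest r, all above 0.9999, included RPS2 with AT4G26095, F3H with AT3G51238, FER1 with AT5G01595, YCF37 with AT2G23672, CYP81F4 with AT4G37409 and MT2B with AT5G02370. The others were AT1G23050 with AT1G23052, AT3G22070 with AT3G22072, AT3G05905 with AT3G05900, and AT1G71528 with AT1G71530. In 9 of the 10 the genes overlapped on opposite strands, and the libraries were not stranded, so the same fragments can count for each and these values are uncertain.

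**Figure D5:**
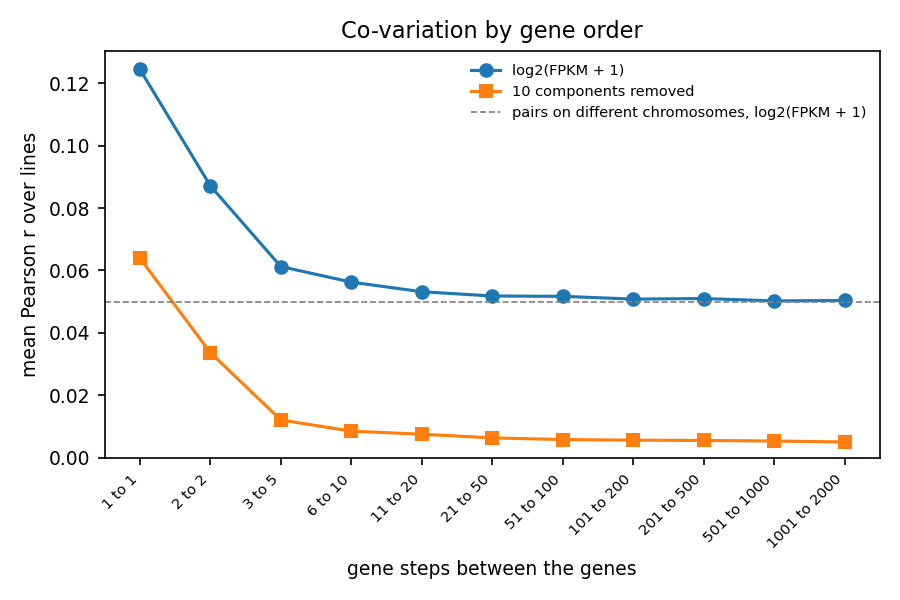
Mean Pearson r over 209 lines between expressed genes by the number of gene steps between them, for pairs that neither overlap nor have similar sequence at 1 step (circles, log2(FPKM + 1); squares, with 10 components removed). The circles fall from 0.124 at 1 step towards 0.0499, the mean for pairs on different chromosomes (dashed line).

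The second component (5.09% of variance) went with the scores of defence lists, whose genes entered it. It rose with the salicylic acid score (r = 0.915, rho = 0.844; 0.894 without the 2 farthest lines; 0.929 in set A and 0.904 in set B) and the NLR score (r = 0.7001, rho = 0.644; 0.660; 0.782 and 0.754), and the wall-associated kinase gene WAK1 (AT1G21250) had the highest correlation with it among genes. The third component (4.04%) fell with light harvesting (r = -0.660, rho = -0.671; -0.679; -0.520 and -0.769) and dark starvation scores (r = -0.645, rho = -0.595; -0.641; -0.578 and -0.734). It rose with ribosome (r = 0.538, rho = 0.485; 0.521; 0.397 and 0.697) and aliphatic glucosinolate scores (r = 0.533, rho = 0.494; 0.506; 0.451 and 0.604). It also rose with iron homeostasis (r = 0.524, rho = 0.504; 0.540; 0.544 and 0.504) and cell division scores (r = 0.485, rho = 0.463; 0.479; 0.392 and 0.537). It also fell with the share of FPKM in the 100 highest genes (r = -0.600, rho = -0.597; -0.595; -0.540 and -0.727), as did the second component less strongly (r = -0.379, rho = -0.331; -0.358; -0.384 and -0.331), and these 2 relations were added after the data were seen. Relations of components with list scores were not in the plan either. The genes of these lists entered the components, so part of each such relation holds by construction and its p value may be too small. Each of these had a permutation p of 1e-05 for r and for rho and adjusted p of 2.46e-05 and 2.65e-05 over 69 relations. The first component splits the libraries, so its relations were taken within sets: with genes detected r was 0.451 in set A and 0.585 in set B, and with the same share -0.422 and -0.631 (permutation p = 1e-05 for each). None of these 4 passed after upper quartile scaling.

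The rank-based table gave a similar order of lines for most genes. For expressed genes the median rho over lines between FPKM and the table was 0.967, with 0.913 and 0.993 at the 5th and 95th percentiles. RBCS1A (AT1G67090), the highest gene, had 1 distinct value there over all lines.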

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

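Features outside the comparisons also carried signal. With no control samples, the bound was 3 fragments, the limit a count of 0 allows, and it covers counting error only. Of 15230 transposable element features with a recovered length, 8.07% had a median above 3 fragments, and 95 of these had an SD of log2(FPKM + 1) above 1. Of 368 unannotated gene features with a recovered length, 43.2% had a median above 3 fragments, and 18 of these had an SD above 1. Whether fragments of other genes add to these values was not tested.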

How the results depend on the processing

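Removal of set means, the minimum of 10 fragments and the exclusion of overlapping and similar neighbours together were chosen after seeing the data. The number of lists with a larger spread was 12 or 13 in every alternative run (13 as designed), and that of co-varying lists 16 to 18 (17). The mean r of neighbouring genes stayed above the shuffles in all 12 alternatives (0.0827 to 0.143). Counts that moved over 1.5 times follow their own thresholds: 9961 detected genes at a minimum of 5 FPKM (16964 at 1), 168 on/off genes at limits of 0.05 and 1 FPKM, 35 at 0.2 and 5 FPKM, and 43 with at least 20 lines on each side. With a pseudocount of 0.1, 589 genes had an SD above 1, sharing 7 of the 10 largest with the design. Removing 10 components left 23 pairs of list scores past the threshold, 9 of them shared with the 74, as that step takes out variation common to many genes. Among named pairs it turned light harvesting with ribosome to 0.0796, aliphatic glucosinolates with flavonoids to -0.194 and with dark starvation to 0.00277, and EDS1 with PAD4 to -0.0657, MYB28 with CYP79F1 to -0.189, MAF2 with MAF3 to -0.282 and RBCS1A with LHCB1.1 to 0.0263. Of these, aliphatic glucosinolates with flavonoids (adjusted p = 0.0297), MYB28 with CYP79F1 (0.00977) and MAF2 with MAF3 (8e-05) passed in the opposite direction. Of 16 named relations of list scores it ended the calls of 9 others, salicylic acid defence with NLR receptors (0.0903) among them, and of 38 gene pairs those of 6 others, CCA1 with TOC1 (-0.117) among them. MAF2 with MAF3 was -0.243 with set means removed. Calls for FRI with FLC, MAF2 with MAF3, BHLH38 with BHLH39, IMA1 with BHLH100 and SPX1 with SQD2 were each lost in several alternatives. FER1 with BHLH39, never past the threshold, changed sign without the 10 farthest lines (0.0224) and by rank (0.00565). RBCS1A with LHCB1.1 had no value in the rank-based table, where RBCS1A is constant. Lists never called changed side of their random median: cell division (0.998 with upper quartile scaling, 0.9997 with set means removed, 1.002 with the median absolute deviation, 0.972 with length matching), light harvesting (0.924 with set means removed, 1.06 with length matching), ribosome (0.968 with set means removed, 0.986 with the median absolute deviation) and stomatal markers (1.15 with length matching). Component 1 held 8.19% of variance with a pseudocount of 0.1, 8.43% without the filter, 8.77% with upper quartile scaling, 8.92% without the 10 lines, and 5.45% with set means removed, which takes out that axis. With upper quartile scaling its relation with genes detected was -0.0826 in set A and -0.100 in set B. The cause was not tested for changes not explained here. Of 76 named SDs, 35 left their interval with a pseudocount of 0.1, 29 with the median absolute deviation, 15 with set means removed and 11 with upper quartile scaling. The median absolute deviation kept 5 of the 10 largest.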

Other observations

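The tests in this part were chosen after the results were seen, except those of chromosome segments for on/off genes and of GC content and length for the first component. Each pattern was found in these data, so any reading is a hypothesis.

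Of 10 root markers 1 was expressed in these aerial samples, and the genes here were named after their values were seen. The root gene PYK10 (AT3G09260), a beta-glucosidase, was at 61.1 ± 21.9 FPKM (SD, n = 209), while the root iron transporter IRT1 (AT4G19690) had a median of 0. PYK10 has 1 near-identical gene and overlaps another, so its value is uncertain. Among cold-responsive genes COR15A (AT2G42540) was at 151.4 ± 86.5 FPKM and CBF3 (AT4G25480) at 9.86 ± 6.37 in plants grown at 20 °C.

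On/off genes fell into 2 kinds: for those with under 10 fragments, counting alone left at least 10 lines off in 78.9% of genes, a median of 41.8% of the off lines at the level in expressing lines and 83.1% at the mean over all lines, so too few fragments may account for many of them. For those with at least 10, counting alone left fewer than 1 line off in 100% of genes at the level in expressing lines. The bound of 10 fragments at that same level nearly fixes this result, so it cannot decide the cause. At the mean level over all lines, counting left a median of 3.21e-05% of their off lines, which argues against counting as the general cause. A near-identical gene was found for 18.9% of them, which argues against shared reads as the general cause. Off calls of 11 pairs within 20 gene steps had a median r of 0.140, narrowly above the 95th percentile of pairs on different chromosomes (0.131), with 6 of the 11 pairs above it. Without genes under 10 fragments and without overlapping or similar pairs, 9 pairs had the same median, and 5 were above the 95th percentile (0.129). Variants of chromosome segments carried by some lines are therefore a candidate explanation, and genotypes were not analysed here. An off call means few counted fragments, and loss of fragments from alleles that differ from TAIR10 was not tested.

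Co-variation of neighbours had at least 2 parts. Of the 10 pairs with the highest r, 9 overlapped, so fragments counted for each gene may account for these. Pairs that did not overlap in the annotation used had a mean r of 0.130, and pairs neither overlapping nor similar 0.124, against at most 0.0559 and 0.0558 in shuffles. Overlap in that annotation therefore does not account for the rest. That annotation may differ from the build used for counting. MT2B with AT5G02370 did not overlap there but had r = 0.99993, so some of these pairs may still share fragments. Inherited chromosome segments may contribute, since r squared at 21 to 200 gene steps with 10 components removed averaged 0.0117, against at most 0.00867 in shuffles. Shared regulation of close neighbours was not tested and stays open.

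On the first component the split of sets A and B may reflect a batch of libraries, since 194 of 200 lines lay on their set's side of a line number. For set C only a batch that follows line number was argued against. Its lines had the higher number in 45.4% of pairs with a line of set A. In the order of samples in the series, all 9 lines of set C stood at the end, from line 198 to line 241, with some lines of set A among them. A batch that follows that order is therefore a candidate for set C and was not tested. Mean depth rose in the order of the sets (10.6, 12.8 and 14.8 M fragments in A, B and C), but depth as the whole cause was argued against, since r with depth was at most 0.0877 in size within sets A and B, over 4.15 to 30.2 M fragments in set B. A few abundant genes were argued against for the split between sets, since 100% of lines stayed on their set's side after upper quartile scaling, but for the order within sets they cannot be told apart from other causes, as r with the share of the 100 highest genes was -0.631 in set B, between the bounds chosen. Across genes, which are not independent, the correlation with the component had a rho of -0.158 with GC content and 0.139 with transcript length, between the bounds set beforehand, so these cannot be told apart from other causes of part of the pattern. Line number may also follow growth order or relatedness among lines, the labels give neither, and no biological explanation of the split was tested. The component did rise with scores of flowering time (r = 0.717 pooled, 0.372 in set A and 0.223 in set B) and the clock (0.293, 0.508 and 0.381). With reference genes it fell when pooled and rose within sets (-0.412, 0.236 and 0.453). The genes of these lists entered the component, so these values cannot decide between causes.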
